A study of Mus musculus with 4 samples.

How the data were processed

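RNA-seq libraries of 4 mouse livers were analysed. Per the labels, the livers lacked Cpt1a and came from mice fasted for 24 h, total RNA was purified from frozen liver with TRIzol and RNeasy columns, and Novogene made the libraries. The labels do not say that the 4 libraries, called 4 livers here, come from separate mice, so the spread between them may be technical. It was more than counting error, with a chi-square per gene of 20.5 to 68.1 between pairs.

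The authors aligned reads with HISAT2 to GRCm38 (mm10), per the submitters' processing notes. The counter, the annotation release and the use of strand are not given in the sources used here. The gene table holds raw read counts per gene as deposited, with gene coordinates, biotype and the authors' gene model length in bases. A companion table holds FPKM as deposited by the authors, that is, counts per kilobase of gene and per 1e6 of a library size. That library size, worked out from the counts, the lengths and the FPKM, was 1.06 to 1.15 times the sum of the deposited counts. The count table also holds 8 per-sample columns that match no sample of this series, and these were not used in any step.

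A further 3 tables hold the authors' own comparisons, with a log2 fold change, a p-value and an adjusted p-value per gene, per the file headers. The tables set the Cpt1a knockout against a reference group, a Cpt2 group against that reference group, and the Cpt1a knockout against the Cpt2 group. The short name of the reference group joins Rab30 and Cpt2, and the sources used here do not say what it stands for. The design text names littermate controls, and says that the Cpt2 samples belong to an earlier series. The test and filter behind the tables, and the number of libraries per group, are not given in the sources used here. Whether the libraries of the Cpt1a knockout were sequenced with those of the other groups is not given either, so a batch and the genotype cannot be told apart.

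Because the series holds 1 group of samples, no test between groups could be fitted from its libraries. Genes were therefore called from the authors' adjusted p below 0.05 and the sign of the authors' log2 fold change, with no SD or n. The table of the Cpt1a knockout against the reference group lists only the 4461 genes with an unadjusted p of at most 0.05. Its adjusted values fit an adjustment over about 16862 genes. For 4424 of its genes the sum of the log2 fold changes in the other tables could be compared, and Pearson's r across genes was 0.999989 with a median difference of 0.012. That sum was used where a value was needed for every gene. An adjusted p of 1 was read as not adjusted.

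The design, the alternatives, 38 gene lists (26 of pathways and other gene groups and 12 of cell types) and the rule for named genes were fixed before the data were examined. The rule named Cpt1a, Cpt2, and in each comparison the 8 protein-coding genes with the smallest adjusted p in each direction among those with an absolute log2 fold change of at least 1. It also named the 4 members of each list with the smallest adjusted p, and let other members stand as examples. For the livers it named the 10 genes with the highest mean FPKM, the 10 with the largest spread at a mean FPKM of at least 5, and the 3 most abundant members of each list. Genes named outside the rule are said to be chosen after their values were seen. A further 5 lists were added after seeing the data: interferon-stimulated genes outside chromosome 1, Kupffer cell residency genes, pan-macrophage genes, lysosome and phagocyte damage genes, and cytosolic ribosomal proteins.

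Lists were tested with cameraPR of limma 3.58.1 (R 4.3.3) on a signed z score made from the authors' p, two-sided, with a preset inter-gene correlation of 0.01. For the partial table, Fisher's exact test asked per direction whether list members were called more often than the other genes. Its background was the 17054 genes with an adjusted p in both other tables, of which 2366 were called, and 65 called genes lay outside it. Benjamini-Hochberg adjustment ran over all 38 lists, and over both directions for Fisher's test. The 5 added lists were adjusted together with these 38. Counts of called members are given over all genes and adjusted over the list alone. As an alternative, the inter-gene correlation of each list was estimated from the 4 livers. These livers belong to neither group in the comparison of the Cpt2 group with the reference group. Estimates below 0 were set to 0. Some lists, such as mitochondrial genome genes and lymphocyte and neutrophil markers (0 each), had an estimate below the preset 0.01. For such lists, passing with the estimate is no stricter check. For the partial table that alternative was cameraPR on the summed log2 fold change of genes with a mean count of at least 10. Other alternatives were the log2 fold change as the statistic, a minimum mean count of 10, and 10000 random lists matched on mean FPKM.

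On simulated data over the same genes, cameraPR recovered 6 of 6 shifted lists for the Cpt1a knockout against the Cpt2 group (23745 genes) and 6 of 6 for the Cpt2 group against the reference group (23373 genes). In each it called 0 of 23 unshifted lists. Fisher's test recovered 3 of 3 lists for the Cpt1a knockout against the reference group (17054 genes) and called 0 of 24 unshifted lists. The simulated genes were independent of each other, so these simulations cannot show how often lists of correlated genes are called falsely. The comparisons of the Cpt1a knockout and of the Cpt2 group share the reference libraries, so unchanged groups were simulated 100 times with the error correlation that the standard errors of the 3 tables give. On 4000 simulated genes that step returned correlations of 0.302 and 0.502 for true values of 0.3 and 0.5.

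Levels are the mean and SD of the authors' FPKM over 4 livers. Spread is the SD of log2(FPKM + 1) over genes with a mean FPKM of at least 1. A list mean is the mean of log2(FPKM + 1) over its members with that level. CPM (counts scaled to library size) with TMM factors came from edgeR 4.0.16. Coordinates are those of the count table on GRCm38, 1-based. For 54409 of its 54532 genes the GENCODE vM21 annotation held the same identifier, on the same chromosome and overlapping in each case. The pseudogene match used BLAST 2.17.0. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. Total counts of 13138884 to 14116441 per liver set the depth, and a count of 0 allows a level of up to 3 counts, or 0.213 to 0.228 CPM, for counting error only. Members of gene families with near-identical copies (Mup, Ifi200, Cyp4a, Cyp2d, Acot, Saa and globin genes, Rpl34 and its pseudogene) are uncertain, since the handling of shared reads is not given. Overlapping and antisense genes are uncertain for the same reason.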

Results

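Livers of mice that lack Cpt1a in the liver were profiled by RNA-seq after a 24 h fast. Cpt1a encodes the liver form of carnitine palmitoyltransferase 1, the outer mitochondrial membrane enzyme that commits long-chain fatty acids to mitochondrial oxidation. Cpt2 encodes the inner membrane enzyme that completes the same transfer. The design asks what each enzyme contributes to the liver transcriptome of fasted mice. The series holds 1 group of 4 livers with 14106038, 13138884, 14116441 and 13682887 counts, in which 19732 to 20258 genes had a count. Comparisons with other groups come from 3 tables of the authors and carry no SD or n.

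Cpt1a (ENSMUSG00000024900, chromosome 19, 3323301 to 3385732, plus strand, GRCm38) remained detectable at 24.4, 28.6, 31.1 and 36.9 FPKM in the 4 livers, from 1574 to 2496 counts. In the authors' deposited table against the reference group it was 6.91-fold lower (log2 fold change −2.79, adjusted p = 5.27e-51). Its muscle form Cpt1b was at 0.211 ± 0.028 FPKM (SD, n = 4), and the brain form Cpt1c at 0.060 ± 0.039. Cpt2 (ENSMUSG00000028607, chromosome 4, 107903981 to 107923610, minus strand) was at 74.0 ± 12.95 FPKM (SD, n = 4). The authors' deposited table of the Cpt2 group against the reference group gave Cpt2 a log2 fold change of −0.07 (adjusted p = 0.837), so the transcript was not lower there. A count over the whole gene need not show the deletion of a part of it. That group is called the group labelled Cpt2 knockout, or the Cpt2 group.

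The livers were rich in mitochondrial and secretory transcripts. The 10 most abundant genes by mean FPKM were mt-Co1 (22884 ± 2951 FPKM, SD, n = 4), Alb (15479 ± 3733), mt-Cytb, mt-Nd2, mt-Nd1, Mup3, Apoa2, mt-Nd6, mt-Nd4 and Apoa1 (4504 ± 2059), which code for respiratory chain subunits, albumin, a major urinary protein and apolipoproteins. Cyp4a14, a fatty acid omega-hydroxylase, was at 3518 ± 1092 FPKM, and Acaa1b, the peroxisomal thiolase, at 1785 ± 406 (SD, n = 4 each). Fasn, fatty acid synthase, was at 2.62 ± 0.189 FPKM (SD, n = 4). Kupffer cell genes were present, with Clec4f at 36.9 ± 2.38 and Lyz2 at 44.9 ± 4.66 FPKM (SD, n = 4 each).

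Over 10859 genes the median SD between livers was 0.20 on the log2(FPKM + 1) scale, a factor of 1.15, and 114 genes had an SD above 1. Pairs of livers correlated across genes with Pearson's r of 0.953 to 0.981. The 10 genes with the largest spread were Gm21320, Mup15, Mup17, Mup5, Mup13, Gm17828, mt-Nd3, Gm17720, mt-Ta and Gm5805. The 5 that led this order lie in the major urinary protein cluster of chromosome 4, where reads are hard to assign. Mup17 ranged from 5.57 to 823 FPKM, while the more abundant Mup3 stayed between 5599 and 7655 FPKM. For mt-Nd3, liver 1 had 366 FPKM and the other 3 livers 18.7, 25.0 and 25.8, so its mean rests on 1 liver. Mitochondrial genes took 8.79 to 10.9% of counts.

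**Figure D1:**
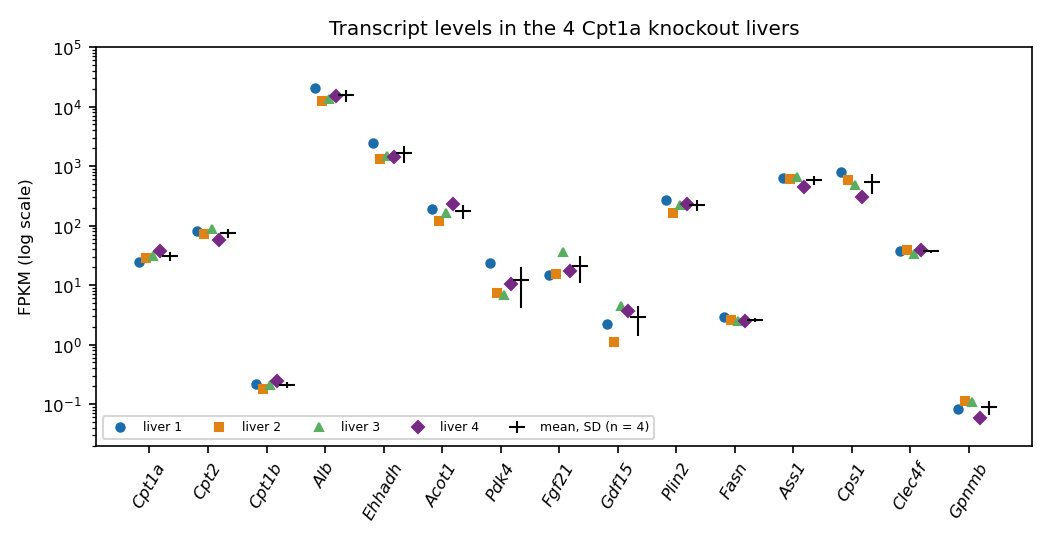
FPKM (log scale) of 15 genes in each of the 4 Cpt1a knockout livers, with the mean and SD (n = 4) drawn to the right. Cpt1a lay between 24.4 and 36.9 FPKM in all 4 livers, and Ehhadh was 2449 FPKM in liver 1.

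Compared with the reference group, the Cpt1a knockout livers had less transcript of genes for amino acid breakdown and the urea cycle and of hepatocyte markers. They had more transcript of genes of the mitochondrial genome. Lymphocyte markers were higher in 4 of 13, and only 2 of 13 reached a mean FPKM of 1 in the knockout livers. The lists named so far were called by Fisher's exact test and with an estimated correlation. Unfolded protein response, periportal and PPARA target genes were called by Fisher's exact test but not with an estimated correlation. Ehhadh, a bifunctional enzyme of peroxisomal beta-oxidation, rose 4.77-fold and Ass1, argininosuccinate synthase of the urea cycle, was 3.66-fold lower in the authors' deposited table. The authors' deposited table called 2431 genes, 1149 higher and 1282 lower, of which 644 and 465 changed at least 2-fold. That is 14.4% of about 16862 genes tested.

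Besides Ehhadh (log2 fold change 2.25, adjusted p = 1.33e-17), the most firmly higher genes in the authors' deposited table were Rpl34, Rarres1, Ifi204, Dgkh, Olfr1033, Mme and Zfp874a. Rarres1, a gene first described as induced by retinoids, had a log2 fold change of 4.29 (adjusted p = 5.79e-34), and Dgkh, a diacylglycerol kinase, 2.62 (3.14e-21) in the authors' deposited table. Mme, the peptidase neprilysin, had 4.31 (2.42e-18), Zfp874a 1.83 (5.08e-18) and Olfr1033, annotated as an odorant receptor, 9.99 (2.42e-18) in the authors' deposited table. The genes most firmly lower in the authors' deposited table were Cpt1a, Car14 (−2.42, adjusted p = 1.11e-37), Ass1 (−1.87, 1.35e-25), Atp1b1, a sodium pump subunit (−2.94, 2.08e-25), and Tpmt (−2.39, 3.07e-24). They also included Pygl, liver glycogen phosphorylase (−1.55, 5.01e-24), Agt, angiotensinogen (−1.68, 3.79e-19), and Plg, plasminogen (−1.77, 7.22e-19), in the authors' deposited table.

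Of 47 measured target genes of PPARA, the nuclear receptor that drives fatty acid use in fasting, 19 were higher and 1 lower in the authors' deposited table (23 and 2 adjusted over the list alone). The adjusted p of this list was 7.38e-10 by Fisher's exact test, and adjusted p = 0.168 with an estimated correlation. Its members Acot1 and Acot2, acyl-CoA thioesterases, had log2 fold changes of 2.40 and 2.58, and Cd36, a fatty acid transporter, 2.71 in the authors' deposited table. Peroxisomal beta-oxidation and proliferation genes were higher in 12 and lower in 4 of 35 (14 and 5 adjusted over the list alone) in the authors' deposited table, with Acaa1b at 1.44 and Crot at 1.44, and Phyh, which starts the breakdown of branched fatty acids, at −0.55. This list had an adjusted p of 1.67e-05 by Fisher's exact test, and adjusted p = 0.498 with an estimated correlation. Mitochondrial beta-oxidation genes passed in 3 higher and 1 lower of 21 (3 and 1 adjusted over the list alone), the lower one being Cpt1a itself, in the authors' deposited table (Fisher's exact test, adjusted p = 0.396). Decr1 had a log2 fold change of 0.63 and Eci1 of 0.59 in the authors' deposited table. Carnitine enzymes and carriers had 3 higher and 1 lower of 13 (adjusted p = 0.146 by Fisher's exact test), with Crat at 0.68, and ketogenesis genes 1 higher of 8 (0.781), in the authors' deposited table.

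Omega-oxidation genes split, with 3 higher and 5 lower of 17 (3 and 6 adjusted over the list alone) in the authors' deposited table. Aldh3a2, which oxidises fatty aldehydes, had a log2 fold change of 1.53, and Cyp4f14 one of −1.47 in the authors' deposited table. Fisher's exact test called the lower direction (adjusted p = 0.0301) although the median of this list was 0.07, and adjusted p = 0.673 with an estimated correlation. Lipid droplet and triglyceride genes had 3 higher and 5 lower of 28 in the authors' deposited table (Fisher's exact test, adjusted p = 0.146), with Cidec at 1.74 and Fitm1 at 2.17 against Lpin1 at −3.07. De novo lipogenesis genes were higher in 2 and lower in 9 of 20 (the same counts adjusted over the list alone) in the authors' deposited table, among them Acly (−1.17), Fasn (−1.87) and Srebf1 (−1.47). For this list the adjusted p was 4.79e-05 by Fisher's exact test, and adjusted p = 0.168 with an estimated correlation. Cholesterol synthesis genes were lower in 6 of 25 and higher in none (7 and 1 adjusted over the list alone) in the authors' deposited table, with Dhcr7 at −1.13. The adjusted p of this list was 0.0328 by Fisher's exact test, and adjusted p = 0.510 with an estimated correlation.

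Genes of amino acid catabolism and the urea cycle were lower in 20 of 24 and none higher (22 adjusted over the list alone) in the authors' deposited table. Tat, tyrosine aminotransferase, had a log2 fold change of −2.38, and Gldc, of glycine cleavage, of −1.61 in the authors' deposited table. The adjusted p of this list was 8.86e-18 by Fisher's exact test and 0.0274 with an estimated correlation. Gluconeogenesis genes were lower in 12 and higher in 2 of 21 (15 and 4 adjusted over the list alone) in the authors' deposited table, with G6pc, glucose-6-phosphatase, at −1.25, Fbp1 at −0.78 and Sds at −1.61. Tested by Fisher's exact test, the list had an adjusted p of 4.96e-08, and adjusted p = 0.148 with an estimated correlation. Bile acid synthesis and transport genes were lower in 7 of 21 and higher in none (8 adjusted over the list alone) in the authors' deposited table, with Akr1d1 at −1.10 and Abcb11, the bile salt export pump, at −1.14. The adjusted p of this list was 0.00312 by Fisher's exact test, and adjusted p = 0.159 with an estimated correlation.

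Genes of the unfolded protein response of the endoplasmic reticulum are called protein folding genes here, though some, such as Edem1, act in protein degradation. They were lower in 15 of 18 and higher in none (16 adjusted over the list alone) in the authors' deposited table. The chaperones Hspa5, Hsp90b1 and Calr had log2 fold changes of −1.54, −1.44 and −1.42, and Pdia6 of −1.60 in the authors' deposited table. Fisher's exact test gave an adjusted p of 1.93e-13, and adjusted p = 0.0630 with an estimated correlation. Mitochondrial chaperones and proteases were lower in 7 of 12 (9 adjusted over the list alone) in the authors' deposited table, with Clpx at −1.22 and Lonp1 at −0.83. They had an adjusted p of 5.71e-05 by Fisher's exact test, and adjusted p = 0.168 with an estimated correlation. Protein-coding genes of the mitochondrial genome were higher in 5 of 12 and lower in none (6 adjusted over the list alone), with mt-Co2 at 1.40 and mt-Atp6 at 1.30, in the authors' deposited table. Their adjusted p was 0.00391 by Fisher's exact test and 0.00218 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 6 lower of 35 (adjusted p = 0.127), ATF4 target genes 5 lower of 29 (0.156) and NRF2 and glutathione genes 1 higher and 1 lower of 22 (1) by Fisher's exact test on the authors' deposited table. Among them Ndufs1 was at −0.86, Asns at −1.64, Gstp1 at −1.12 and Srxn1 at 0.56 in the authors' deposited table.

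Secreted liver factors fell in 9 and rose in 1 of 26 (10 and 2 adjusted over the list alone), with Ahsg at −1.44, in the authors' deposited table. Acute phase genes were lower in 8 and higher in 1 of 22 (8 and 2 adjusted over the list alone) in the authors' deposited table, with the fibrinogen chains Fga, Fgb and Fgg at −1.41, −1.36 and −1.27 and Il1b, a macrophage cytokine, at 2.78. The adjusted p by Fisher's exact test were 4.19e-04 and 6.67e-04 for these lists, and adjusted p = 0.222 and 0.130 with an estimated correlation. Drug metabolism genes had 3 higher and 5 lower of 18, Cyp3a11 at −1.33, and male-biased genes 5 lower of 14 (6 adjusted over the list alone), Cyp7b1 at −1.48, in the authors' deposited table. Their adjusted p were 0.0328 and 0.0125 by Fisher's exact test, and adjusted p = 0.138 and 0.501 with an estimated correlation. Circadian clock genes split into 5 higher and 5 lower of 19 in the authors' deposited table, with Nr1d1 at 1.54 and Arntl, which it represses, at −2.06. Fisher's exact test called both directions (adjusted p = 0.0316 higher and 0.0376 lower) at a median of −0.28, and adjusted p = 0.673 in the lower direction with an estimated correlation.

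Among cell type markers, those of hepatocytes were lower in 6 of 11 and none higher (7 adjusted over the list alone) and periportal markers lower in 13 of 15 in the authors' deposited table, with Pigr at −1.53 and Aldh1b1 at −2.28. Fisher's exact test gave adjusted p of 4.12e-04 and 3.43e-12, which became 9.54e-05 and, for the periportal list, adjusted p = 0.0564 with an estimated correlation. Lymphocyte markers were higher in 4 of 13 (4 adjusted over the list alone), Ptprc at 1.29 and Cd79b at 2.45, in the authors' deposited table (Fisher's exact test, adjusted p = 0.0335 and 1.48e-05 with an estimated correlation). Ptprc is a gene of white blood cells in general and does not mark lymphocytes alone. Pericentral markers had 4 higher and 4 lower of 15 (adjusted p = 0.0521), Kupffer cell markers 2 higher of 15 (0.583, but 0.00553 against random lists), Lyz2 at 1.31, endothelial markers 1 higher of 11 (0.957) and stellate cell markers 2 higher of 11 (0.396) by Fisher's exact test on the authors' deposited table. Neutrophil markers had 1 higher of 3 and adipocyte markers 2 lower of 5, and bile duct, red blood cell and exocrine pancreas markers none of 9, 4 and 2, in the authors' deposited table (Fisher's exact test, adjusted p of 0.144 to 1). Female-biased, proliferation and extracellular matrix genes had 1 higher and 1 lower of 6, 1 and 3 of 18, and 1 and 1 of 19 in the authors' deposited table (Fisher's exact test, adjusted p of 0.710 to 1), with Acot3 at 2.72, Cdkn1a at −2.84 and Tgfb1 at 0.91. Of 19 lists called by Fisher's exact test, 5 were called with an estimated correlation, 4 of them among the 19, and the fifth was the neutrophil list (adjusted p = 0.0349). Among these 5, the estimate was 0 for mitochondrial genome, lymphocyte and neutrophil genes and 0.0076 for hepatocyte markers. These estimates lie below the preset 0.01, so they do not show that the calls withstand correlated genes. Amino acid and urea cycle genes passed with an estimate of 0.27. Other alternatives ended the calls of peroxisomal (adjusted p = 0.144 with the log2 fold change as statistic, 0.173 against random lists), omega-oxidation (0.341 with the log2 fold change), cholesterol (0.0632 at a mean count of at least 10), clock (0.0502 at that count) and drug metabolism genes (0.258 against random lists).

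**Figure D2:**
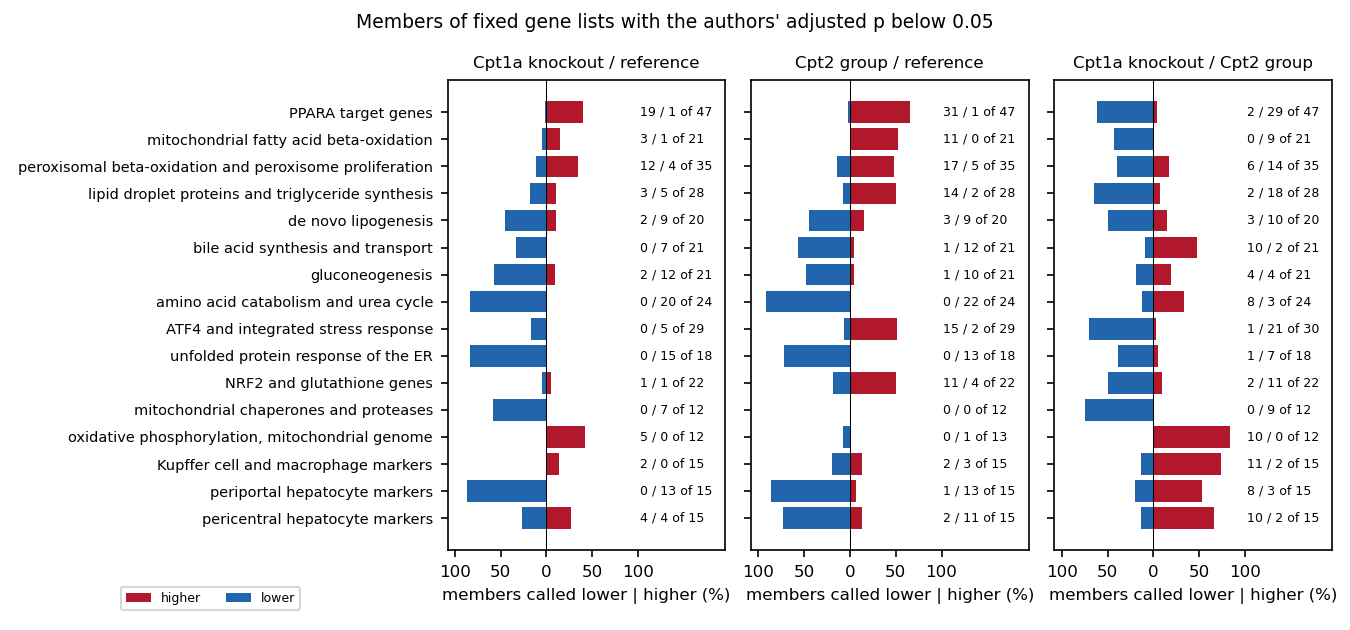
Share of the measured members of 16 gene lists that were lower (left, blue) or higher (right, red) at an adjusted p below 0.05 in the authors' 3 deposited tables, in percent. Counts at the right are higher, lower and measured members, such as 20 lower of 24 amino acid and urea cycle genes in the Cpt1a knockout.

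Some of the largest changes were local to a stretch of genome or shared by near-identical copies. Rpl34 (chromosome 3, 130726831 to 130730398), a ribosomal protein gene, had log2 fold changes of 6.06 and 5.48 in the Cpt1a knockout and the Cpt2 group in the authors' deposited tables. Its processed pseudogene Rpl34-ps1 (chromosome 6, 71124610 to 71124963), chosen after its values were seen, had −4.41 and −5.00 there in the authors' deposited tables. All 354 bases of the pseudogene align to an Rpl34 transcript with 2 mismatches (99.4% identity), so which of both genes a read is counted for is uncertain. The Ifi200 cluster of innate immune genes lies at 173350879 to 174031810 on chromosome 1. Ifi204 was 7.98-fold and 3.97-fold higher, and Mndal, chosen after its values were seen, had log2 fold changes of 8.62 and 7.31 in the authors' deposited tables of the Cpt1a knockout and the Cpt2 group. Of 27 immune genes within 3 Mb of the cluster, 20 were called in the Cpt1a knockout, 19 of them higher, in the authors' deposited table. Of the 59 other genes there, 15 (25.4%) were called, against 13.7% of the rest of the genome (one-sided Fisher's exact test, p = 0.0122). The Cpt2 group gave 30.5% against 21.1% (one-sided Fisher's exact test, p = 0.0580) from the authors' deposited table.

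**Figure D3:**
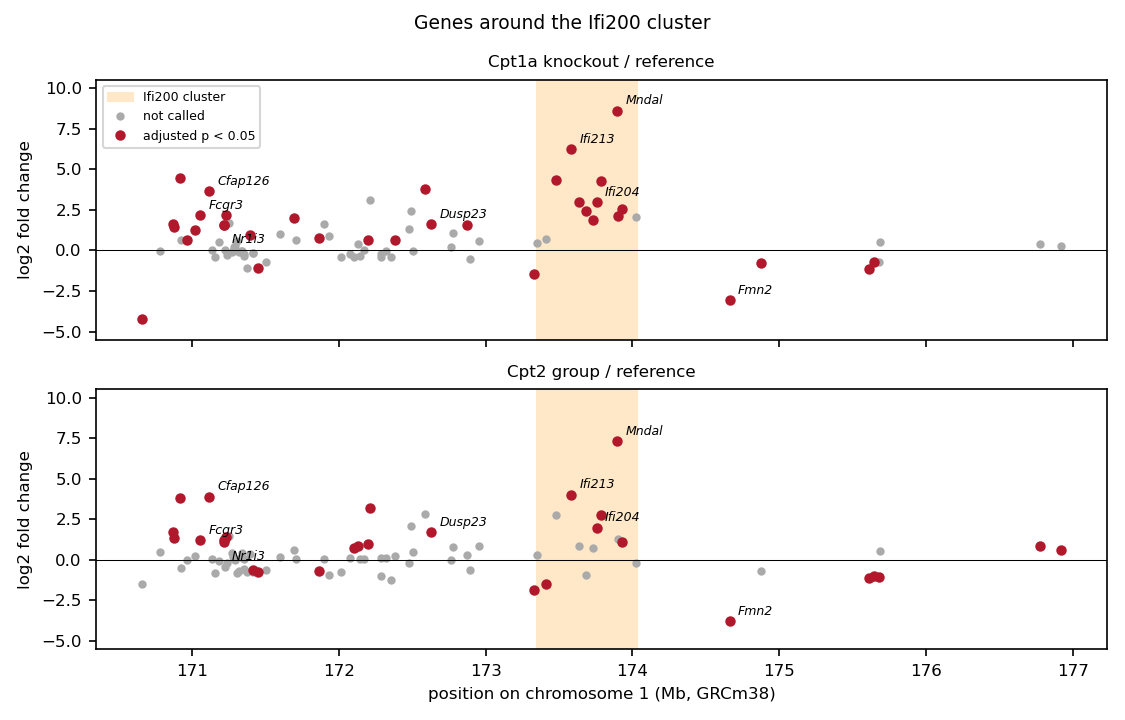
The authors' log2 fold changes of genes on chromosome 1 (position in Mb, GRCm38) around the Ifi200 cluster, shaded, for the Cpt1a knockout and the Cpt2 group against the reference group. Red points had an adjusted p below 0.05, and Mndal lay highest at 8.62 and 7.31.

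The Cpt2 group had higher levels of PPARA, lipid droplet, ATF4 and NRF2 genes than the reference group and lower levels of bile acid, periportal and amino acid genes. Ehhadh rose 9.75-fold, Gpnmb, a lysosomal glycoprotein of phagocytes, 65.6-fold, and Akr1d1, a reductase of bile acid synthesis, was 22.5-fold lower in the authors' deposited table. Cpt1a itself rose 1.65-fold (log2 fold change 0.72, adjusted p = 4.29e-04) in the authors' deposited table. The authors' deposited table called 3675 genes, 1807 higher and 1868 lower, of which 836 and 1011 changed at least 2-fold, or 21.0% of 17475 genes tested.

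After Rpl34 (5.48), the most firmly higher genes in the authors' deposited table were Srxn1, sulfiredoxin (log2 fold change 2.78, adjusted p = 1.83e-84), Sema3b (5.07, 2.11e-66) and Rarres1 (5.25, 1.74e-61). They were followed by Endod1 (4.36), Gpnmb (6.04), Ehhadh (3.28) and Elovl7, a fatty acid elongase (6.12), the last with an adjusted p of 2.47e-50, in the authors' deposited table. The most firmly lower were Saa4 (−4.38, adjusted p = 9.67e-88), Akr1d1 (−4.49, 8.21e-56), Cyp3a11, a steroid and drug oxidase (−3.23), Ass1 (−2.02) and Hsd11b1, which regenerates glucocorticoids (−2.19), in the authors' deposited table. Proz, a coagulation protein (−2.27), Ppp1r3b, which targets a phosphatase to glycogen (−3.32), and Car14 (−3.32) completed that set in the authors' deposited table.

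PPARA target genes were higher in 31 and lower in 1 of 47 (34 and 2 adjusted over the list alone) in the authors' deposited table, with Pdk4, which restrains pyruvate oxidation, at 3.83, Plin2 at 2.59 and Fgf21 at 2.74. Their adjusted p was 2.82e-34 by cameraPR and 2.47e-04 with an estimated correlation. Mitochondrial beta-oxidation genes were higher in 11 of 21 and lower in none (11 and 2 adjusted over the list alone), Hadha at 0.98 and Acadl at 0.85, and peroxisomal genes in 17 and 5 of 35 (19 and 5 adjusted over the list alone), Pex11a at 1.77, in the authors' deposited table. cameraPR gave adjusted p of 1.97e-05 and 1.01e-06, and 0.0335 and 0.0108 with an estimated correlation. Carnitine genes had 5 higher and 1 lower of 13, Crat at 1.34, and ketogenesis genes 4 higher of 8 (5 adjusted over the list alone), the monocarboxylate transporter Slc16a6 at 1.43, in the authors' deposited table (cameraPR, adjusted p = 0.00807 and 0.0134). Lipid droplet genes were higher in 14 and lower in 2 of 28 (17 and 2 adjusted over the list alone), Cidec at 3.51 and Plin4 at 2.27, in the authors' deposited table (cameraPR, adjusted p = 8.13e-10). ATF4 and integrated stress response genes were higher in 15 and lower in 2 of 29 (18 and 2 adjusted over the list alone), Psat1 at 4.74 and Nupr1 at 4.60 against Cth at −3.09, in the authors' deposited table (cameraPR, adjusted p = 1.48e-07). NRF2 and glutathione genes were higher in 11 and lower in 4 of 22, Cbr3 at 4.12 and Gsr at 1.14, in the authors' deposited table (cameraPR, adjusted p = 1.46e-09).

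Amino acid and urea cycle genes were lower in 22 of 24 (22 adjusted over the list alone), Otc at −2.10, and periportal markers lower in 13 and higher in 1 of 15 (14 and 1 adjusted over the list alone), Aldh1b1 at −3.10, in the authors' deposited table. cameraPR gave adjusted p of 2.78e-32 and 7.67e-23, and 6.43e-06 and 4.21e-04 with an estimated correlation. Bile acid genes were lower in 12 and higher in 1 of 21 (13 and 1 adjusted over the list alone), Nr0b2, the repressor SHP, at −3.95 and Abcb11 at −2.58, in the authors' deposited table (cameraPR, adjusted p = 1.75e-12). Gluconeogenesis genes were lower in 10 and higher in 1 of 21 (11 and 1 adjusted over the list alone), G6pc at −2.76, and protein folding genes in 13 of 18 (15 adjusted over the list alone), Edem1 at −1.28, in the authors' deposited table (cameraPR, adjusted p = 1.23e-07 and 4.41e-09). Hepatocyte markers were lower in 8 of 11, Alb at −1.41, and pericentral markers lower in 11 and higher in 2 of 15 (11 and 3 adjusted over the list alone), Slc1a2 at −2.51, in the authors' deposited table (cameraPR, adjusted p = 9.40e-10 and 1.23e-07). Secreted factors had 12 lower and 4 higher of 26 (13 and 4 adjusted over the list alone), Enho at −3.56, and drug metabolism genes 9 lower and 3 higher of 18 (10 and 4 adjusted over the list alone), Cyp2c50 at −1.47, in the authors' deposited table (cameraPR, adjusted p = 3.17e-06 and 2.33e-04). All lists of this paragraph kept an adjusted p below 0.05 with an estimated correlation. The estimates came from the Cpt1a knockout livers, which belong to neither group compared here. For hepatocyte markers the estimate of 0.0076 lies below the preset 0.01, so that check was no stricter. With the log2 fold change as statistic the calls ended for gluconeogenesis (adjusted p = 0.0641), protein folding (0.0572), secreted (0.417), drug metabolism (0.121) and pericentral genes (0.0530), and for beta-oxidation (0.236), carnitine (0.308) and ketogenesis genes (0.273).

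Lists lost with an estimated correlation were cholesterol synthesis (7 lower of 25, 8 adjusted over the list alone), acute phase (10 lower of 22, 13 adjusted over the list alone, Saa3 at −3.06), male-biased (7 lower of 15, C6 at −1.42) and circadian clock genes (9 lower and 4 higher of 19, 11 and 4 adjusted over the list alone, Nfil3 at −2.97) in the authors' deposited table. Their adjusted p of 2.99e-04, 2.28e-04, 2.28e-04 and 0.0161 by cameraPR became adjusted p = 0.274, 0.128, 0.176 and 0.102 with an estimated correlation. Nuclear genes of oxidative phosphorylation (3 lower of 35, 2 adjusted over the list alone, Sdhb at −0.80) and red blood cell markers (4 lower of 5, Hbb-bs at −1.42) had adjusted p of 0.0323 and 0.00682 by cameraPR on the authors' deposited table, and adjusted p = 0.578 and 0.318 with an estimated correlation. Bile duct markers were lower in 2 of 9, Sox9 at −2.27, in the authors' deposited table (cameraPR, adjusted p = 0.0401 and 0.0413 with an estimated correlation, but 0.0806 with the log2 fold change, 0.0771 at a mean count of at least 10 and 0.0602 against random lists). Lipogenesis genes had 3 higher and 9 lower of 20 (4 and 10 adjusted over the list alone; cameraPR, adjusted p = 0.0937), Thrsp at −2.79 and Elovl5 at 1.65, in the authors' deposited table. The remaining 13 lists were not called by cameraPR on the authors' deposited table (adjusted p of 0.209 to 0.671). These were omega-oxidation, extracellular matrix, mitochondrial genome, mitochondrial chaperone, proliferation and female-biased genes, and markers of Kupffer, endothelial, stellate, lymphocyte, neutrophil, adipocyte and exocrine pancreas cells. Among them Cd68, a lysosomal marker of macrophages, was at 2.60, while Vsig4 and Clec4f of Kupffer cells were at −0.65 and −0.69 in the authors' deposited table.

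Set directly against the Cpt2 group, the Cpt1a knockout livers had lower levels of lipid droplet, ATF4 and NRF2 genes. Lymphocyte markers were higher there in 4 of 13, and only 2 of 13 reached a mean FPKM of 1 in the knockout livers. Gpnmb was 45.1-fold lower and Akr1d1 10.4-fold higher in the Cpt1a knockout in the authors' deposited table. Cpt1a was 11.5-fold lower (log2 fold change −3.52, adjusted p = 7.11e-82), and Cpt2 had a log2 fold change of 0.45 (adjusted p = 0.0607) in the authors' deposited table. The authors' deposited table called 5106 genes, 2514 higher and 2592 lower, or 28.8% of 17755 tested, and 1189 and 713 of them changed at least 2-fold.

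The most firmly higher genes in the authors' deposited table were Slc22a30 (log2 fold change 3.20, adjusted p = 1.54e-54), Saa4 (3.06), Adra1b, an adrenergic receptor (3.04), Car8 (2.05), Serpina6, the plasma carrier of glucocorticoids (3.26), Apol7a (2.35), Akr1d1 (3.38) and the chemokine Cxcl12 (1.55). The most firmly lower after Cpt1a were Gpnmb (adjusted p = 1.54e-72), Elovl7 (−5.46), Tubb2a, a tubulin (−3.67), Endod1 (−3.47), Srxn1 (−2.23), Pgd, an NADPH-producing enzyme (−1.91), and Ccdc120 (−3.29) in the authors' deposited table. Gpnmb stood at 0.090 ± 0.025 FPKM and Elovl7 at 0.125 ± 0.062 FPKM (SD, n = 4) in the Cpt1a knockout livers.

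PPARA target genes were lower in 29 and higher in 2 of 47 (30 and 2 adjusted over the list alone), Fabp3 at −6.49, Pdk4 at −3.21 and Plin2 at −2.09, in the authors' deposited table. Mitochondrial beta-oxidation genes were lower in 9 of 21 (10 lower and 2 higher adjusted over the list alone), Hadha at −0.84, in the authors' deposited table. cameraPR gave adjusted p of 2.26e-12 and 3.37e-05, and adjusted p = 0.0547 for both with an estimated correlation. Carnitine genes had 4 lower and 2 higher of 13 (4 and 3 adjusted over the list alone), Crat at −0.67, and peroxisomal genes 14 lower and 6 higher of 35 (17 and 6 adjusted over the list alone), Ehhadh at −1.05 and Pecr at 1.18, in the authors' deposited table. Their adjusted p of 0.0123 and 0.0331 by cameraPR became adjusted p = 0.0547 and 0.318 with an estimated correlation. Cpt1a itself (−3.52) is a member of the carnitine and beta-oxidation lists, which were not tested without it. The carnitine list had a median of −0.02, and adjusted p = 0.651 against random lists. Lipid droplet genes were lower in 18 and higher in 2 of 28 (20 and 3 adjusted over the list alone), Cidec at −1.79 and Hsd17b13 at −1.35, in the authors' deposited table (cameraPR, adjusted p = 4.06e-13, and 3.59e-05 with an estimated correlation). Lipogenesis genes had 10 lower and 3 higher of 20 (11 and 4 adjusted over the list alone), Acacb at −1.36 and Thrsp at 1.79, in the authors' deposited table (cameraPR, adjusted p = 0.00510). That call was lost, with adjusted p = 0.184 with an estimated correlation.

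ATF4 and integrated stress response genes were lower in 21 and higher in 1 of 30 (22 and 1 adjusted over the list alone), Nupr1 at −5.32, Atf3 at −2.97 and Mthfd2 at −2.74, in the authors' deposited table (cameraPR, adjusted p = 4.06e-13, and 4.56e-04 with an estimated correlation). NRF2 and glutathione genes were lower in 11 and higher in 2 of 22 (12 and 2 adjusted over the list alone), Cbr3 at −3.49 and Ugdh at −1.79, in the authors' deposited table (cameraPR, adjusted p = 2.06e-09). Mitochondrial chaperones and proteases were lower in 9 of 12 (11 adjusted over the list alone), Lonp1 at −0.87 and Hspd1 at −0.85, in the authors' deposited table (cameraPR, adjusted p = 9.75e-10). With an estimated correlation both were called (adjusted p of 2.13e-06 and 1.13e-04), but the chaperone list was not with the log2 fold change as statistic (0.0781). Protein folding genes of the endoplasmic reticulum had 7 lower and 1 higher of 18, Hsp90b1 at −0.87, in the authors' deposited table (cameraPR, adjusted p = 0.0495). Adjusted p = 0.518 with an estimated correlation ended that call.

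Genes of the mitochondrial genome were higher in 10 of 12 (11 adjusted over the list alone), mt-Nd2 at 0.78 and mt-Nd5 at 0.95, in the authors' deposited table (cameraPR, adjusted p = 3.37e-05, and 3.59e-05 with an estimated correlation, but 0.201 with the log2 fold change as statistic). Bile acid genes were higher in 10 and lower in 2 of 21, Nr0b2 at 3.07 and Slco1a1 at 1.94, and pericentral markers higher in 10 and lower in 2 of 15, Glul, glutamine synthetase, at 1.73, in the authors' deposited table. Their adjusted p of 1.20e-04 and 3.37e-05 by cameraPR became adjusted p = 0.132 and 0.0694 with an estimated correlation. Kupffer cell and macrophage markers were higher in 11 and lower in 2 of 15, Lyz2 at 1.66, Vsig4 at 1.19 and Timd4 at 1.48 against Cd68 at −2.18, in the authors' deposited table (cameraPR, adjusted p = 5.47e-05). With an estimated correlation the macrophage list had adjusted p = 0.0547. Lymphocyte markers were higher in 4 of 13, Ptprc of white blood cells in general at 1.42, and endothelial markers in 4 of 11, Clec4g at 0.79, in the authors' deposited table (cameraPR, adjusted p = 0.00297 and 0.0178). With an estimated correlation both were called (adjusted p of 0.00293 and 0.0369), but the endothelial list was not with the log2 fold change (0.748), at a mean count of at least 10 (0.0716) or against random lists (0.125). The estimates of 0 for lymphocyte and 0.0091 for endothelial markers lie below the preset 0.01, so that check was no stricter. Red blood cell markers (4 higher of 5, Alas2 at 1.04), male-biased genes (6 higher and 2 lower of 14, Mup3 at 1.23) and clock genes (7 higher and 2 lower of 19, 9 and 4 adjusted over the list alone, Nfil3 at 1.72) had adjusted p of 0.00213, 0.0495 and 0.0466 by cameraPR on the authors' deposited table. With an estimated correlation these were lost (adjusted p = 0.260, 0.531 and 0.210).

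A further 19 lists were not called between the Cpt1a knockout and the Cpt2 group by cameraPR on the authors' deposited table (adjusted p of 0.0699 to 0.974). Amino acid genes had 8 higher and 3 lower of 24, Otc at 1.28 and Cps1, the entry enzyme of the urea cycle, at −1.21, and periportal markers 8 higher and 3 lower of 15, Ctsc at 1.80, in the authors' deposited table. Cholesterol genes had 9 higher and 5 lower of 25, gluconeogenesis genes 4 and 4 of 21, Fbp1 at 0.89, secreted factors 11 and 10 of 27, Apoa4 at −3.10, and drug metabolism genes 7 and 6 of 18 in the authors' deposited table. Acute phase genes had 6 higher and 2 lower of 24, Saa3 at 2.90, and nuclear genes of oxidative phosphorylation 10 and 6 of 35 in the authors' deposited table. The others were omega-oxidation, ketogenesis, extracellular matrix, proliferation and female-biased genes, and markers of hepatocytes, stellate, bile duct, neutrophil, adipocyte and exocrine pancreas cells. Over all lists, 248, 335 and 364 members were called in the Cpt1a knockout against the reference, the Cpt2 group against the reference and the Cpt1a knockout against the Cpt2 group (285, 371 and 399 adjusted over the list alone) in the authors' deposited tables. Where no count adjusted over the list alone stands beside a called list, such as the lymphocyte markers, that count was the same.

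Many genes changed the same way in the Cpt1a knockout and the Cpt2 group. Against the reference group, 1061 of 17054 genes present in the authors' deposited tables were called with the same sign, 400 higher and 661 lower. Independent lists of these lengths would share 119 and 131. Unchanged groups simulated against the shared reference libraries gave 23.1 same-sign pairs on average (at most 35 in 100 simulations) at the same p, and 0 after adjustment. Across 13761 genes, which are not independent replicates, the log2 fold changes correlated at Pearson's r = 0.523. The simulated unchanged groups had 0.618, but for z scores of equal variance over all 17054 genes, so these values cannot be compared. The covariance of the log2 fold changes was 0.30 against 0.076 simulated, a difference of 0.22. Both simulated values rest on 3990 genes with a p of at most 0.05 in the Cpt1a knockout against the reference group. Both comparisons share the reference libraries, so part of the excess over independent lists or simulations may come from them. These libraries were not split, since per-sample columns outside this series were not used. Ass1 (−1.87 and −2.02), Plg (−1.77 and −1.62) and Acot1 (2.40 and 2.85) had similar values in the authors' deposited tables. In the authors' deposited tables, 2030 genes were called in the Cpt2 group against the reference group and, with opposite sign, in the direct comparison. Independent lists would give 532, and simulations gave 14.3 on average. The Cpt2 libraries enter these comparisons with opposite sign, so a change in that group alone gives this pattern by construction. Against the reference group, a smaller set of 76 genes was called with opposite signs, 26 higher in the Cpt1a knockout and 50 higher in the Cpt2 group. All 76 were also called between the groups in the authors' deposited tables. Opposite changes add up in the direct comparison, so those calls largely follow from the others. Besides Cpt1a the 76 genes included the keratin gene Krt8 (−0.84 and 0.89) and Iars, a transfer RNA synthetase (−0.79 and 0.64), chosen after their values were seen, in the authors' deposited tables.

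**Figure D4:**
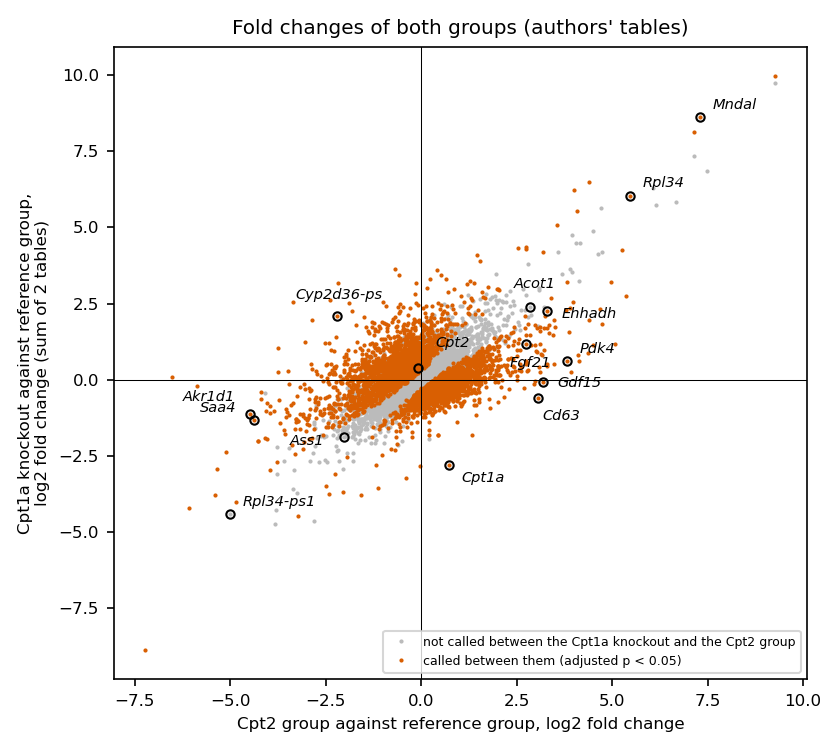
Log2 fold changes against the reference group of genes with a mean count of at least 10, in the Cpt2 group (horizontal) and the Cpt1a knockout (vertical, sum of the other 2 deposited tables). Orange genes were called between the groups, and labelled genes outside the naming rule were chosen after their values were seen; Rpl34 lay at 5.48 and 6.04.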

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

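The tests on Rpl34, the chromosome 1 window and macrophage markers were chosen after the results were seen. For the test on genes of all macrophages the prediction was written before its value was seen, but its list was among those added after seeing the data. Bootstrap intervals in this part were drawn over genes, which are not independent, and not over livers. Of 93 groups of 4 liver values, 11 held 1 liver far from the other 3, and chance alone marks about 1 group in 20. The groups include genes named for their large spread, such as Mup17, Mup5 and mt-Nd3, so the count cannot be set against that share. The mean log2(FPKM + 1) of lipid droplet genes was 4.90 in liver 2 against 5.12, 5.11 and 5.14 in the others. Lipogenesis genes had a mean of 4.01 in liver 2 against 4.196, 4.179 and 4.195, and cholesterol synthesis genes 2.94 in liver 2 against 3.15, 3.17 and 3.15. ATF4 and integrated stress response genes had a mean of 4.35 in liver 3 against 3.99, 4.01 and 4.02. Exocrine pancreas markers had a mean of 2.22 in liver 1 against 1.05, 1.12 and 1.20, and Prss2 had 2.37 FPKM in liver 1 and no count in the other livers. Ehhadh stood at 2449 FPKM in liver 1 against 1289, 1470 and 1404, and mt-Nd3 at 366 FPKM in liver 1 against 18.7, 25.0 and 25.8. Mup5 was at 31.8 FPKM in liver 1 against 0, 0 and 1.38, and Mup17 at 823 FPKM in liver 2 against 61.8, 5.57 and 45.6. Ass1 was at 439.8 FPKM in liver 4 against 620, 613 and 646, and Zfp874a at 3.81 FPKM in liver 4 against 5.08, 5.05 and 4.99.

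The Cpt1a knockout and the Cpt2 group differed from each other in 5106 genes in the authors' deposited table. Among these were 76 genes called with opposite signs against the reference group in the authors' deposited tables. On the same table, 19 gene lists were called between the groups by cameraPR, against 7 with an estimated correlation and 8 with the log2 fold change as statistic, 6 of these among the 19.

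Rpl34 rose and its processed pseudogene Rpl34-ps1 fell against the reference group in the Cpt1a knockout and the Cpt2 group in the authors' deposited tables. The log2 change of both genes combined was 0.55 and −0.013, and the sequences match at 99.4%, which favours reads moving between near-identical copies. It speaks against a rise of Rpl34 transcript as large as that of Rpl34 alone, but not against a smaller one. In the Cpt1a knockout the 0.55 lies near the median of 0.66 over 85 genes of cytosolic ribosomal proteins. The fold changes imply 45.0 reference counts for Rpl34 and 2061 for Rpl34-ps1, where the Cpt1a knockout livers had 2990 and 97 on average. A variant of Rpl34-ps1 or Rpl34 between the mice or another handling of the reads may lie behind the shift and was not tested.

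Genes of the Ifi200 cluster and its neighbours on chromosome 1 were higher in the Cpt1a knockout than in the reference group in the authors' deposited table. Among genes of that window outside immune families, 25.4% were called against 13.7% elsewhere (one-sided Fisher's exact test, p = 0.0122), as a segment from another strain would predict. Against an interferon response or more macrophages alone, 32 interferon-stimulated genes on other chromosomes had a median log2 fold change of 0.21 (bootstrap 95% interval 0.012 to 0.48) beside 2.76 in the cluster, and 14 macrophage markers elsewhere 0.49 (0.22 to 0.59) beside 2.15 for the window's immune genes. Between the Cpt1a knockout and the Cpt2 group, 18 immune genes of the window were called, 17 of them higher, while its other genes were called in 15.3% against 29.5% elsewhere (one-sided Fisher's exact test, p = 0.996) in the authors' deposited table. Between these groups, interferon-stimulated genes outside chromosome 1 were higher in 23 of 32 with a median of 1.01, and macrophage markers had a median of 0.83. An interferon response or more macrophages is therefore not excluded for the immune genes called between the groups. A strain difference from the reference group may explain part of the block, but does not account for those genes. No sequence was at hand to test it.

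Macrophage markers were higher in the Cpt1a knockout than in the Cpt2 group in the authors' deposited table, with a median log2 fold change of 0.83 over 15 genes, of which 2 were lower (Cd68 at −2.18), and the call was lost with an estimated correlation (adjusted p = 0.0547). Endothelial, stellate and bile duct markers had a median of 0.18, a difference of 0.65 (permutation p = 0.00499), which speaks against a lower share of hepatocyte RNA as the only source. The permutation shuffled genes, which are not independent replicates, and does not measure the spread between livers. Hepatocyte markers had a median of 0.07 between the groups, with 2 higher and 1 lower of 11. Lymphocyte markers, also called higher, had a median of 1.42, in a list that includes Ptprc, which does not mark lymphocytes alone. Neutrophil markers had a median of 1.47 with 1 called of 5 (cameraPR, adjusted p = 0.270). Red blood cell markers had 1.04, but that call was lost with an estimated correlation (adjusted p = 0.260). No test compared these medians with that of macrophage markers. Genes of all macrophages had a median of 0.63 (bootstrap 95% interval 0.22 to 0.92) and Kupffer residency genes 0.94, so whether Kupffer cells alone differ stays open. More macrophages in 1 group, or a shift in their state, could each give these values.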

How the results depend on the processing

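No paired analysis was possible because the series holds only 1 group of samples. For the Cpt1a knockout against the reference group, protein-coding genes alone, a mean count of at least 10 and no filter gave 2092, 2394 and 2143 called genes, of which 2092, 2293 and 2140 were among the 2431 reported. Stricter thresholds lowered the counts by their construction, to 1390 at an adjusted p below 0.01 and 1109 at a 2-fold change. A 2-fold change left 1902 of 5106 genes between the Cpt1a knockout and the Cpt2 group and 1847 of 3675 in the Cpt2 group, and 646 (adjusted p below 0.01) or 499 (2-fold) of 1061 shared calls. At 2-fold, 58.1% of called genes were higher in the Cpt1a knockout against the reference group (47.3% of all called) and 62.5% against the Cpt2 group (49.2%); the cause was not tested. An estimated correlation called 5 lists in the Cpt1a knockout, 4 of them among the 19 reported, and 7 between the groups, all among the 19. Some of these lists, such as the lymphocyte markers, had an estimate below the preset 0.01, where this setting is no stricter. The log2 fold change as statistic called 8 lists between the groups, 6 of them among the 19, and 12 in the Cpt2 group, 10 of them among the 24; the cause was not tested. Of 453 list results under alternatives, 323 kept direction and side of the threshold, 80 were weaker, 11 stronger and 39 lay in the other direction. Apart from the ties named below, the cause was not tested. Clock genes in the Cpt1a knockout, called in both directions by Fisher's exact test and counted as higher by the smaller p, lay in the lower direction without a call with the log2 fold change (adjusted p = 0.451), an estimated correlation (0.673) and random lists (0.109). Against random lists the direction also turned there for omega-oxidation (adjusted p = 0.677), female-biased (0.0114), pericentral (0.0258) and bile duct genes (0.00532), and for adipocyte markers in the Cpt2 group (0.0173, median 1.23 over 5 genes). In the Cpt1a knockout against the reference group, no bile duct or red blood cell marker was called. Fisher's exact test gave them equal p in both directions, and such ties were recorded as higher. Turns of these lists are therefore not reversals of a result. Calls gained, the 11 stronger results, were neutrophil (0.0130 with the log2 fold change, 0.0349 with an estimated correlation, 0.0258 against random lists) and Kupffer cell markers (0.00553, random lists) in the Cpt1a knockout, female-biased (0.0154) and pancreas genes (0.00574) in the Cpt2 group and both between the groups (0.0385 and 8.11e-06) with the log2 fold change, and pancreas genes in both (0.0182 and 0.0019) and periportal markers between the groups (0.0076) against random lists. The other 31 of the 39 were called under neither setting. In the Cpt1a knockout against the reference group, with the log2 fold change and with an estimated correlation, these were beta-oxidation (adjusted p = 0.580, 0.8001), carnitine (0.973, 0.981), lipid droplet (0.981, 0.988), extracellular matrix (0.491, 0.773), female-biased (0.625, 0.773), pericentral (0.580, 0.8001), bile duct (0.208, 0.242) and red blood cell genes (0.660, 0.841). Against random lists they were lipid droplet (0.201), ATF4 (0.939), extracellular matrix (0.659), proliferation (0.939) and red blood cell genes (0.981) there, and mitochondrial genome genes in the Cpt2 group (0.508). Between the Cpt1a knockout and the Cpt2 group they were cholesterol (0.875), gluconeogenesis (0.748), nuclear oxidative phosphorylation (0.822), proliferation (0.728) and hepatocyte genes (0.875) with the log2 fold change, and gluconeogenesis (0.201), secreted (0.982), proliferation (0.0954) and bile duct genes (0.691) against random lists. Of 2228 results on named genes, 2091 were the same, 133 weaker and 4 stronger. Cpt1a at 30.3 FPKM was 78.9 in TPM and 146 in TMM-scaled CPM, a change of unit, and 28.0 to 32.2 FPKM with each liver left out. The median SD of 0.20 was 0.25 with a pseudocount of 0.1, 0.14 without the filter and 0.25 on TMM-scaled CPM, and 0.166 (without liver 1) to 0.208 with each liver left out. For the chromosome 1 window, flanks of 1, 2 and 5 Mb gave p = 0.00171, 0.0370 and 0.0164 (one-sided Fisher's exact test). Depth limits a gene without a count to 0.213 to 0.228 CPM.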

Other observations

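The lists of this part were added after seeing the data. Tests of a cause that used the interferon and pan-macrophage lists are given above, and no other such test was run on these lists. Genes of cytosolic ribosomal proteins were higher in 38 of 85 (42 adjusted over the list alone) in the Cpt1a knockout against the reference group in the authors' deposited table (Fisher's exact test, adjusted p = 7.02e-21). With an estimated correlation this list had adjusted p = 0.329. Against the Cpt2 group 28 were higher and none lower (29 adjusted over the list alone), and in the Cpt2 group against the reference group 10 (7 adjusted over the list alone), in the authors' deposited tables. Their adjusted p of 2.06e-07 and 1.07e-05 by cameraPR became adjusted p = 0.478 and 0.5004 with an estimated correlation. Rps6 and Rps2 of the small subunit, chosen after their values were seen, had log2 fold changes of 0.77 and 0.67 in the Cpt1a knockout in the authors' deposited table. The list includes Rpl34, whose own change is uncertain as described above. Reads shared with near-identical copies were not examined for its other members.

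Interferon-stimulated genes outside chromosome 1 were higher in 23 of 32 and none lower (25 adjusted over the list alone) in the Cpt1a knockout against the Cpt2 group in the authors' deposited table (cameraPR, adjusted p = 5.50e-11). They were lower in 7 (8 adjusted over the list alone) in the Cpt2 group against the reference group (cameraPR, adjusted p = 1.64e-05) and higher in 3 in the Cpt1a knockout (Fisher's exact test, adjusted p = 0.728) in the authors' deposited tables. Irf7, a transcription factor of the interferon response, had log2 fold changes of 1.63 and −1.16, and the antiviral genes Ifit1 and Rtp4 1.59 and 1.43 between the groups, chosen after their values were seen, in the authors' deposited tables. Lysosome and phagocyte damage genes were lower in 10 of 16 (10 lower and 1 higher adjusted over the list alone) in the Cpt1a knockout against the Cpt2 group in the authors' deposited table (cameraPR, adjusted p = 1.50e-12). In the Cpt2 group against the reference group 8 were higher and 3 lower (8 and 5 adjusted over the list alone), and 3 were lower in the Cpt1a knockout, in the authors' deposited tables (adjusted p = 1.66e-05 by cameraPR and 0.293 by Fisher's exact test). Cd63, a protein of late endosomes, had −3.65 and Lgals3, galectin-3, −1.73 between the groups in the authors' deposited table, chosen after their values were seen. Ctsl, a lysosomal protease chosen likewise, was lower in the Cpt1a knockout against the reference group at −2.10 in the authors' deposited table.

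Kupffer cell residency genes were higher in 5 of 9 (6 adjusted over the list alone) and pan-macrophage genes higher in 9 and lower in 2 of 15 (10 and 2 adjusted over the list alone) in the Cpt1a knockout against the Cpt2 group in the authors' deposited table. Their adjusted p by cameraPR were 5.60e-05 and 0.00272, and 6.62e-04 and, for the pan-macrophage list, adjusted p = 0.0604 with an estimated correlation. Against the reference group, residency genes had 2 higher in the Cpt1a knockout (Fisher's exact test, adjusted p = 0.3005) and 1 higher and 3 lower in the Cpt2 group (cameraPR, 0.201) in the authors' deposited tables. Pan-macrophage genes had 3 higher and 1 lower in the Cpt1a knockout (Fisher's exact test, adjusted p = 0.214) and 2 higher and 1 lower in the Cpt2 group (cameraPR, 0.551) in the authors' deposited tables. Against random lists, residency and pan-macrophage genes were called higher in the Cpt1a knockout (adjusted p = 0.0195 and 0.00798) and lower in the Cpt2 group (0.0455 and 0.0489), and lysosome genes lower in the Cpt1a knockout (0.0462, and 0.0493 with the log2 fold change). With the log2 fold change as statistic the calls between the groups ended for residency (adjusted p = 0.239), pan-macrophage (0.553) and ribosomal protein genes (0.203), and at a mean count of at least 10 that of lysosome genes in the Cpt2 group against the reference group (0.0640).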
